A study of Gallus gallus with 24 samples.

How the data were processed

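Messenger RNA was measured by sequencing of poly(A)-selected, directional libraries from DF1 cells, a spontaneously immortalised chicken embryonic fibroblast line. The growth label gives a temperature that is unusual for this line and may be a typing error. The 24 libraries formed 8 groups of 3. Mock cells, which the labels give as wild type, and cells with a knockdown of IRF9 were sampled at 0 h, 30 min, 1 h and 6 h of treatment with poly(I:C), a synthetic double-stranded RNA. The labels name poly(I:C) for every sample, the 0 h samples included, and no unstimulated samples of 30 min, 1 h or 6 h were analysed here. How poly(I:C) was given to the cells and how the knockdown was made are not given in the sources used here. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

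Whole-number read counts per gene were deposited by the authors, 1 table per library, with no normalization. Per the submitters' processing notes, FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.7.11b, HTSeq 2.0.5 and edgeR 3.40.2 were used with the chicken genome build GRCg7b. The strand setting of the counting is not given in the sources used here. Counts of overlapping and antisense genes are therefore uncertain. HTSeq listed 3.43 to 4.25% of each library as not uniquely aligned, so genes with near-identical copies, among them the histone and interferon families, may be undercounted. Whether the neighbouring chemokine genes IL8L1 and IL8L2 lost reads in this way was not tested.

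The files held 25466 genes and 5 summary lines of the counter, which stayed out of library sizes and tests. Of those lines, reads in no gene made up 14.6 to 18.8% of a library and ambiguous reads 1.18 to 1.33%. The counts assigned to genes came to 12174030 to 19974065 per library. At this depth, a count of 3 corresponded to 0.150 to 0.259 CPM (counts scaled to a common library total, after TMM), and such floors cover counting error only. Gene identifiers were matched to the supplied GRCg7b gene table, 25216 by symbol and 13 by locus tag, and 237 had no match. Within each group, every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 3.11 to 56.9, so no library was counted as a copy of another.

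From the deposited counts, genes were filtered with filterByExpr, which kept 13000. Libraries were scaled by TMM, and 1 model with 8 group means was fitted to all 24 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. All groups shared 1 estimate of the spread, with 16 residual degrees of freedom and a common biological coefficient of variation of 14.0%. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 13000 genes, and a gene was called changed at an adjusted p under 0.05. Adjusted p-values without another tool's name come from edgeR. Levels are CPM, computed here, as mean ± SD over 3 libraries, and log2 fold changes carry standard errors (SE). IRF9 was also tested by exact permutation of the 6 libraries at each time and by 100000 permutations of genotype within times.

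The comparisons were knockdown against mock at each time and averaged over the 4 times, each later time against 0 h within each genotype, and the interaction of knockdown with each later time. The filter, the model, the comparisons, the alternatives, 24 gene lists and the rule for naming genes were chosen before the data were examined, apart from 4 alternatives described as chosen after seeing the data. By that rule the text names IRF9 and, per comparison, the 10 largest rises and 10 largest falls among called genes. These needed a gene symbol, a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. The rule adds the 4 members with the smallest p of each list, and a gene named in 1 comparison may be given in the others. Genes outside it are described as chosen after their values were seen, and 1 gene that the rule names is not reported here.

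The lists held 985 entries, of which 814 were in the files. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with camera at a correlation estimated for each list, and with fry, which asks only whether a list's genes moved on balance 1 way. Adjusted p-values of lists are over the lists of 1 comparison. Counts of settings that kept a list call leave out fry and the estimated correlation. Single results of fry are not given, and most list calls of camera did not pass it. Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment to the members of that list.

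The labels number the replicates 1 to 3 in every group, and whether equal numbers mark shared cultures or days is not given in the sources used here. The deviations of same-numbered libraries from their group means correlated at 0.174 to 0.441 in the time comparisons of mock cells. Each number was above 0.1, so there the numbers were taken to pair the samples, and in the other comparisons they were not. Deviations within a group balance out, so the shift shared by the mock replicate 2 libraries can alone give such correlations for replicates 1 and 3. The correlations therefore do not show that equal numbers mark shared cultures. On the fourth component of a principal component analysis (6.85% of the variance), the replicate 3 libraries of all 8 groups lay at -17.8 to -8.9. The other libraries lay at 0.105 to 22.6. Replicate 3 thus stood apart in both genotypes at every time, and the cause was not tested. The main fit had no replicate block and did not use the pairing.

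The procedure was tested on simulated data with the real libraries' means and sizes and 50 genes changed per fold size among 13000. The changed genes were drawn from those with a mean of at least 1 CPM, so the shares recovered do not cover genes under that level. For 6 h against 0 h in mock cells, edgeR recovered 44% of changes of 1.5-fold, 74% of 2-fold, 90% of 3-fold and 98% of 4-fold and called 12 unchanged genes. For knockdown against mock at 6 h the shares were 36, 80, 82 and 98%, with 13 unchanged genes called. For the interaction at 6 h they were 18, 72, 74 and 86%, with 6 unchanged genes called. A simulated shift of the interferon-stimulated list by -0.3 (log2) gave an adjusted p of 8.93e-16, or 1.01e-05 with an estimated correlation, and 0 of the 22 other lists were called. The simulated genes varied independently of each other, and no libraries were made to stand apart. This check therefore says nothing about false calls of lists whose genes vary together.

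The alternatives were scaling by the RLE method, no filter on low counts, DESeq2 1.42.0, limma voom, a replicate block, a fit of only the groups compared, and leaving out each library in turn. Those chosen after seeing the data were a block fitted separately within each genotype, leaving out the 4 libraries of mock replicate 2, leaving out both replicate 1 libraries at 30 min, and, for the comparison of the 6 h responses, leaving out genes under 1 CPM in any of the 4 groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.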

Results

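RNA from DF1 chicken fibroblasts was sequenced in 24 libraries, 3 for each of 8 groups: mock and IRF9 knockdown cells at 0 h, 30 min, 1 h and 6 h of poly(I:C). The series concerns the function of IRF9 in the innate antiviral response of the chicken. In mammals, IRF9 acts with STAT2 in a complex that turns on interferon-stimulated genes. Counts in genes ranged from 12174030 to 19974065 per library, and 14883 to 15803 genes had at least 1 count. On a principal component analysis of all libraries, the 4 libraries of mock replicate 2 lay at 29.5 to 39.8 on the first component, and the other 20 lay between -17.8 and 8.58. HSPA2, a heat shock protein gene, took 0.623 to 0.931% of the counts in those 4 libraries and 1.49 to 3.23% in the others.

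**Figure D1:**
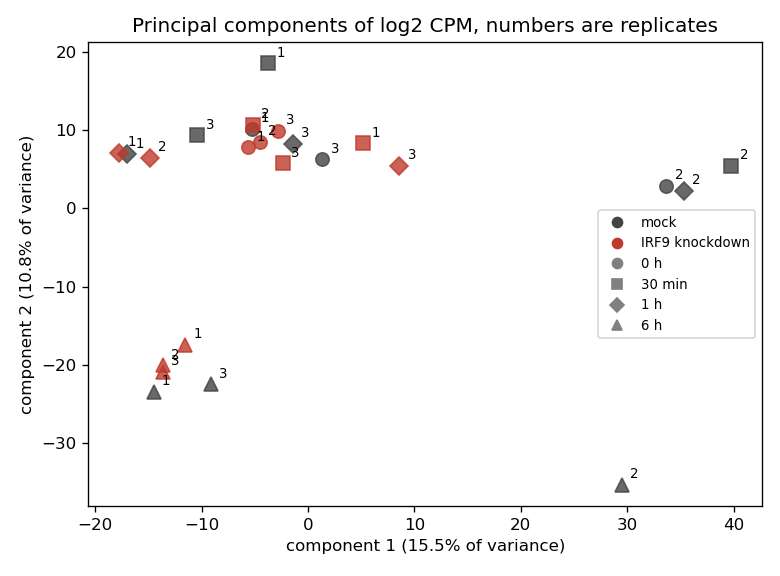
Principal components of log2 CPM for the 24 libraries. The first component (15.5% of the variance) is on the x axis and the second (10.8%) on the y axis, and each point is 1 library. The 4 libraries of mock replicate 2 sit at 29.5 to 39.8 on the first component, apart from the other 20.

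The level of IRF9 came first, since it checks the labels. IRF9 lies on chromosome 20 from 10406021 to 10408887 (GRCg7b, gene identifier 395243, protein-coding), and the reference lists IRF10 as another name for it. Which of these names the knockdown was designed against is not given in the sources used here, so the role of IRF9 in mammals is background only. IRF9 was lower in knockdown than in mock cells at each time, at 17.8 ± 3.30 against 27.6 ± 1.40 CPM at 0 h and 16.0 ± 3.08 against 34.6 ± 9.25 CPM at 30 min (SD, n = 3). At 1 h it was at 15.3 ± 3.96 against 27.0 ± 1.88 CPM, and at 6 h at 21.7 ± 1.29 against 32.8 ± 0.853 CPM (SD, n = 3). The knockdown level was thus 64.5, 46.2, 56.8 and 66.1% of the mock level. No knockdown library overlapped a mock library of the same time, and the two-sided exact permutation p was 0.1 at each time, the smallest that 3 against 3 libraries allow. With genotype permuted within times over all 24 libraries, the permutation p was 3e-05, which takes the libraries as independent. In edgeR the average difference was -0.79 (log2, SE 0.09, adjusted p = 7.67e-05). At single times it passed the threshold over all genes only at 30 min (-1.10, SE 0.18, adjusted p = 0.0316), where the mock replicate 1 library held 45.3 CPM. That call ended without mock replicate 1 at 30 min (-0.87, adjusted p = 0.636), without knockdown replicate 1 (-0.96, adjusted p = 0.672) and without knockdown replicate 2 (-1.10, adjusted p = 0.172). IRF9 itself did not pass the test over 6 h of poly(I:C) in mock cells (0.25, adjusted p = 0.743) or knockdown cells (0.29, adjusted p = 0.663).

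**Figure D2:**
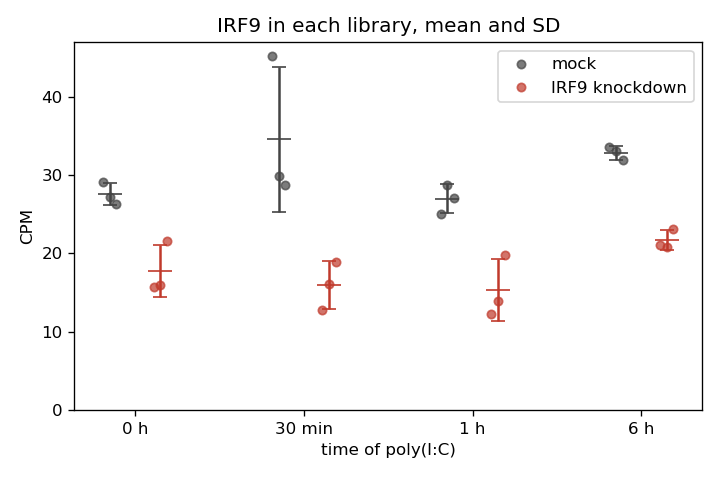
IRF9 level in CPM (y axis) in mock and knockdown cells at each time of poly(I:C) (x axis). Points are libraries, and bars mark the mean and SD of 3. Knockdown libraries reach at most 23.2 CPM and mock libraries are never under 25.0 CPM.

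The first question was what changed in mock cells between 0 h and 6 h of poly(I:C). No unstimulated 6 h samples were analysed, so for every 6 h change, in either genotype, time in culture and poly(I:C) cannot be separated. Genes of inflammatory signalling rose. The chemokine gene IL8L1, a relative of interleukin 8, went from 1.81 ± 0.0978 to 40.7 ± 16.3 CPM (log2 fold change 4.48, SE 0.44, adjusted p = 4.39e-07). The chemokine gene CCL4 went from 369 ± 52.8 to 1608 ± 140 CPM (2.12, SE 0.17, adjusted p = 1.33e-08), and NFKBIA, which encodes an inhibitor of NF-kB, from 121 ± 7.72 to 303 ± 23.9 CPM (1.32, SE 0.10, adjusted p = 6.88e-09). HELZ2, a helicase gene counted among the interferon-stimulated genes, rose from 15.01 ± 3.56 to 144 ± 11.7 CPM (3.27, SE 0.22, adjusted p = 2.51e-09). Each of these levels is the mean ± SD of 3 libraries tested by edgeR. MAP2K6, a kinase gene upstream of p38, fell from 13.6 ± 4.98 to 1.91 ± 0.413 CPM (-2.83, SE 0.37, adjusted p = 2.69e-05). IL8L1 lies on chromosome 4 from 50430778 to 50434071, CCL4 on chromosome 19 from 913750 to 915305, HELZ2 on chromosome 20 from 10074766 to 10097361 and MAP2K6 on chromosome 18 from 8612297 to 8658929 (GRCg7b).

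The largest of the other rises in mock cells at 6 h included the ligand gene TNFSF15 (2.94, SE 0.33), TMEM132B (2.59, SE 0.54), the bradykinin receptor genes BDKRB1 (2.54, SE 0.24) and BDKRB2 (2.07, SE 0.28), the chemokine gene IL8L2 (2.18, SE 0.36), the metalloproteinase inhibitor gene TIMP3 (2.18, SE 0.35) and the growth factor gene PDGFB (2.11, SE 0.19). The falls included TLR3, the endosomal receptor for double-stranded RNA (-1.26, SE 0.27, adjusted p = 0.00797), the homeobox gene IRX1 (-1.12), SYNM (-0.97), TRAIL-LIKE (-0.94), METRNL (-0.93), TRIL (-0.90), MAB21L2 (-0.83) and LZTS1 (-0.82). In all, edgeR called 282 genes, 252 higher and 30 lower, in the main fit, which did not use the replicate numbers. With the replicate number as a block fitted within each genotype, an alternative chosen after seeing the data, it called 699, 510 higher and 189 lower. A fit of only these 6 libraries called 155. Without the 4 libraries of mock replicate 2, 204 genes were called.

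Among the gene lists in mock cells at 6 h, 9 of the 18 tested genes for interferons, cytokines and chemokines rose (10 higher and 1 lower when adjusted over the list alone), CSF3, LIF, CX3CL1 and CSF1 among them. The list's median change was 0.92, with an adjusted p of 2.09e-14 by camera and 5.33e-05 with an estimated correlation. Without the low-count filter, when more members were tested, the median was 0.22 (adjusted p = 1.32e-08). Of 37 NF-kB targets and regulators, 16 rose and 0 fell (23 higher adjusted over the list alone), with a median of 0.58 and an adjusted p of 2.5e-27, or 2.25e-07 with an estimated correlation. They included TNIP1 (2.04, SE 0.17), NFKBIZ, NFKB2 and TRAF3 (0.91, SE 0.12). Of 28 genes of sterol synthesis, 18 rose and 0 fell (22 higher adjusted over the list alone), with a median of 0.88 and an adjusted p of 3.04e-36, or 0.0122 with an estimated correlation. HMGCS1, which encodes HMG-CoA synthase, went from 159 ± 37.6 to 501 ± 101 CPM (1.66, SE 0.17, adjusted p = 7.72e-07, edgeR, n = 3), and STARD4, a sterol carrier gene, rose by 1.72 (SE 0.14), LSS by 1.58 (SE 0.17) and NSDHL by 1.30 (SE 0.14).

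Interferon-stimulated genes as a list did not pass the test in mock cells at 6 h. Of 48 tested, HELZ2, CASP8 (0.38), NLRC5 (1.07) and IFI6 rose and TLR3 fell (6 higher and 1 lower adjusted over the list alone). The list's median was -0.04 and its mean 0.09, with an adjusted p of 0.799, or 0.861 with an estimated correlation. IFI6 stood near the floor at 0 h, at 0.0992 ± 0.0524 CPM, and at 1.13 ± 0.414 CPM at 6 h (adjusted p = 0.0339, edgeR, n = 3). MX1 and RSAD2, classical interferon-stimulated genes chosen after their values were seen, had 19 and 4 counts over all 24 libraries and were not tested. Of 29 genes from RNA and DNA sensing to interferon induction, TRAF3 and TRAF2 (0.50) rose and TLR3 fell (3 higher and 1 lower adjusted over the list alone, list adjusted p = 0.174). Of 29 JAK-STAT and IRF genes, the interferon gamma receptor gene IFNGR1 rose (0.50, list adjusted p = 0.939), with 1 higher and 1 lower adjusted over the list alone. NLRC5, a regulator of MHC class I genes, was the 1 called among 21 antigen presentation genes (2 higher adjusted over the list alone).

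Of 47 immediate early genes, 8 rose in mock cells at 6 h (8 adjusted over the list alone), among them SPRY4 (1.04), CYR61 (1.00), BTG2 (0.68) and KLF6 (0.65). The list had an adjusted p of 2.88e-06, and the call was lost with an estimated correlation (adjusted p = 0.708). Its median of 0.28 was 0.088 without mock replicate 1 at 6 h (adjusted p = 0.027), 0.12 without mock replicate 2 at 0 h (adjusted p = 0.00923) and 0.17 without the low-count filter, but 0.46 without mock replicate 2 at 6 h and 0.42 without mock replicate 1 at 0 h. Of 53 extracellular matrix and fibroblast genes, THBS1 (1.24), TIMP3, TAGLN (0.96), CCN2 and TPM1 (0.55) rose (6 adjusted over the list alone, list adjusted p = 0.209). Of 36 apoptosis genes, CASP8 and the death receptor gene TNFRSF10B (0.77) rose (3 adjusted over the list alone). Of 27 p53 targets, BTG2 and TNFRSF10B rose and EDA2R fell (-0.55), with 4 higher and 2 lower adjusted over the list alone. Of 66 cell cycle genes, CDK6 and CCND1 rose (2 adjusted over the list alone). No member was called by edgeR in the lists for the unfolded protein response (29), heat shock (28), oxidative phosphorylation (47), mitochondrially encoded genes (13), histones (13) and epithelial (3) and neural (4) markers, nor any when adjusted over each list alone. The 2 skeletal muscle markers were too few for a list test, and neither was called.

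**Figure D3:**
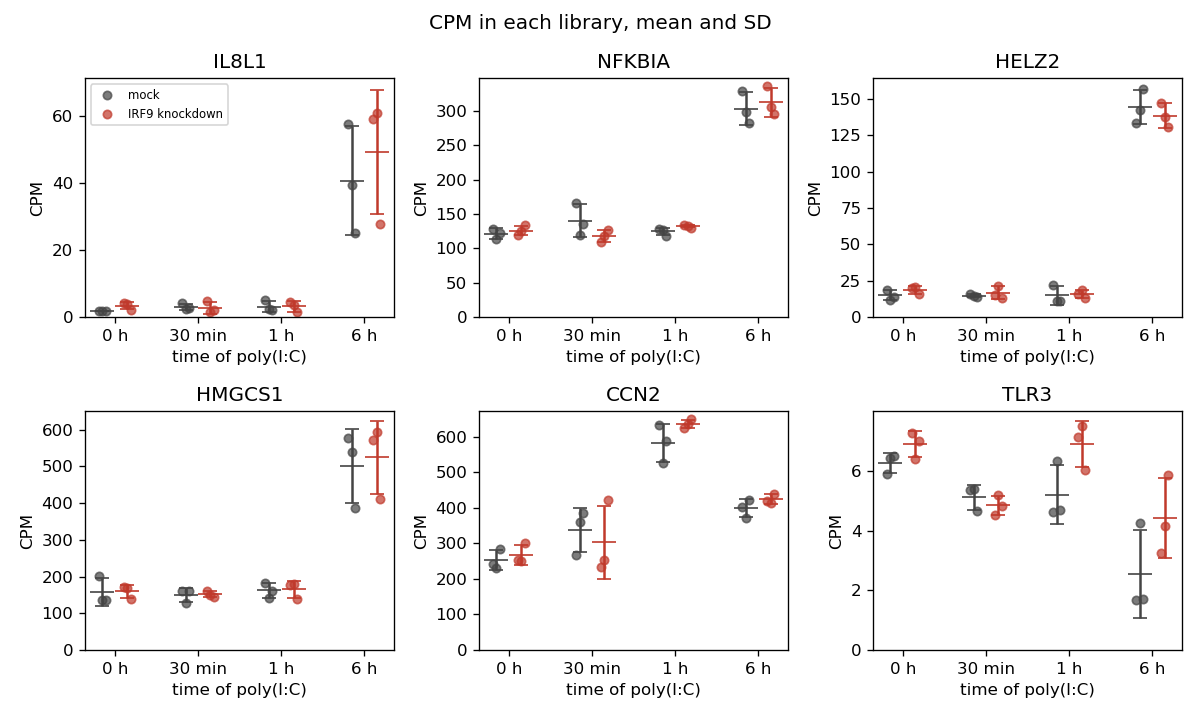
Levels in CPM (y axes) of IL8L1, NFKBIA, HELZ2, HMGCS1, CCN2 and TLR3 by time of poly(I:C) (x axes) in mock and knockdown cells, with points for libraries and the mean and SD of 3. HELZ2 in mock cells is at 15.01 CPM at 0 h and 144 CPM at 6 h, while CCN2 is highest at 1 h in both genotypes.

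In IRF9 knockdown cells, genes of the same lists rose by 6 h of poly(I:C). IL8L1 rose from 3.39 ± 1.08 to 49.2 ± 18.5 CPM (3.85, SE 0.41, adjusted p = 1.34e-06), HELZ2 from 18.7 ± 2.79 to 138 ± 8.30 CPM (2.89, SE 0.22, adjusted p = 1.56e-08) and CCL4 from 362 ± 18.3 to 1586 ± 145 CPM (2.13, SE 0.17, adjusted p = 2.45e-08). CSF3, the gene for granulocyte colony-stimulating factor, rose from 2.79 ± 0.923 to 16.3 ± 5.80 CPM (2.54, SE 0.30, adjusted p = 6.4e-06). These tests were by edgeR with n = 3 per group. BDKRB1 (2.35), IL8L2 (2.14), TNIP1 (2.06), DIO3, a thyroid hormone deiodinase gene (1.93), BDKRB2 (1.92) and the sterol synthesis gene MSMO1 (1.86) completed the 10 largest rises. The largest falls were MAP2K6 (-1.69, SE 0.35, adjusted p = 0.00797), SYT13 (-1.42), PRKCB, a protein kinase C gene (-1.23), IRX1 (-0.95), RGMA (-0.95), LZTS1 (-0.82), ZNF462 (-0.82), EPB41 (-0.75), SYNE1 (-0.74) and NAV2 (-0.74). In all, edgeR called 224 genes, 186 higher and 38 lower. A fit of only these 6 libraries called 843, and the fit without the 4 libraries of mock replicate 2 called 378. Leaving out knockdown replicate 1, 2 or 3 at 0 h gave 125, 120 and 147, and leaving out replicate 1 or 2 at 6 h gave 138 each.

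In knockdown cells at 6 h, 9 of 18 interferon, cytokine and chemokine genes rose (10 adjusted over the list alone), with a median of 0.92 and an adjusted p of 6.42e-15, or 4.5e-05 with an estimated correlation. Of 37 NF-kB genes 13 rose (21 adjusted over the list alone), NFKBIA (1.31) and TRAF3 (0.67) among them, with an adjusted p of 5.64e-24, or 5.8e-07 with an estimated correlation. Of 28 sterol synthesis genes 20 rose (23 adjusted over the list alone), HMGCS1 by 1.71 and LSS by 1.79, with an adjusted p of 3.7e-44, or 0.00526 with an estimated correlation. Of 48 interferon-stimulated genes, HELZ2, CASP8 (0.36), IFI6 and IFIT5 rose (4 adjusted over the list alone), with a median of 0.02 and an adjusted p of 0.813. IFIT5, which encodes an RNA-binding antiviral protein, went from 2.50 ± 0.524 to 6.79 ± 0.671 CPM (1.44, SE 0.29, adjusted p = 0.00624, edgeR, n = 3). IFI6 was at 0.287 ± 0.0137 CPM at 0 h and 3.17 ± 0.875 CPM at 6 h. Of 47 immediate early genes 7 rose (8 adjusted over the list alone), with an adjusted p of 1.17e-08 that was lost with an estimated correlation (adjusted p = 0.325). TLR3 did not pass the test (-0.63, adjusted p = 0.344).

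Whether the 6 h response differed between the genotypes was tested as an interaction. None of the named genes of the response passed this test. The interaction of CCL4 was 0.01 (SE 0.23), of HMGCS1 0.05 (SE 0.23), of HELZ2 -0.38 (SE 0.29), of IL8L1 -0.62 (SE 0.59), of TNFSF15 -1.18 (SE 0.46), of MAP2K6 1.13 (SE 0.51) and of TLR3 0.63 (SE 0.37). IFIT5 had an interaction of 0.42 (SE 0.42) and NLRC5 of -0.56 (SE 0.37), and each of these had an adjusted p of 1. At 6 h edgeR called 0 genes for the interaction, and DESeq2 and limma voom also called 0. In edgeR, 204 genes had an unadjusted p under 0.05 where 650 are expected by chance. The block within genotypes, chosen after seeing the data, gave 452 such genes and called 0. A count under that expected by chance is no evidence that the genotypes responded alike. At 30 min and 1 h all 3 tools called 0, with 750 and 137 genes at an unadjusted p under 0.05 in edgeR. The errors leave room for differences of the size of those of TNFSF15 and MAP2K6.

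Of the genes called at 6 h, 159 rose in both genotypes (252 in mock and 186 in knockdown cells) where independent lists would share 3.61, and 10 fell in both (30 and 38) where independent lists would share 0.0877. These comparisons share no library, but 1 fit gave both the same spread for each gene. A gene of small spread is easier to call in both, so independent lists are a low baseline. Fits of only the groups compared called 155 genes in mock and 843 in knockdown cells, so the order of the counts depends on the fit. Over the 282 genes called in mock cells, 279 had the same sign in knockdown cells, and the changes correlated across genes with Pearson's r of 0.908 and Spearman's rho of 0.921; genes are not independent replicates. Over all 13000 genes tested, r was 0.409, rho 0.415 and the slope 0.38, and 66.3% had the same sign. Over the 282 genes the slope of the knockdown on the mock change was 0.69 (jackknife SE 0.233 over libraries). One gene, LOC395551, chosen after its values were seen, had few counts at 0 h and fitted changes of 8.57 and 4.44, which depend on the prior count. Over the 276 genes with at least 1 CPM in each of the 4 groups, an alternative chosen after seeing the data, the slope was 0.84. Simulations in which both genotypes responded equally gave slopes of 0.592 to 0.771 over all called genes and 0.736 to 0.833 over genes with at least 1 CPM. In them, 43.1 to 54.5% of the genes called in mock were also called in knockdown cells, and in the data 169 of 282 (59.9%). The simulations called 454 genes in mock cells on average, more than the data, so their slopes and shares are over a larger set of genes. Over the 48 interferon-stimulated genes the slope was 0.80, and 34 had the same sign.

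**Figure D4:**
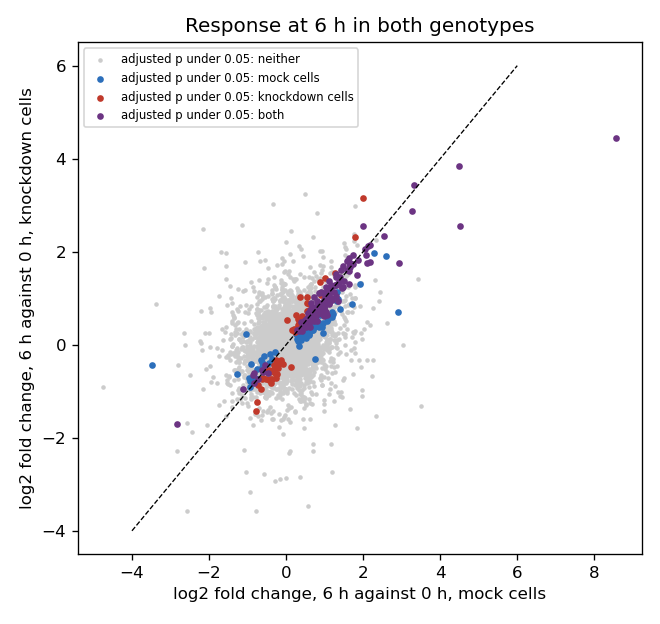
Log2 fold change from 0 h to 6 h in mock cells (x axis) and in IRF9 knockdown cells (y axis), 1 point per gene. The dashed line marks equal changes. Of the 282 genes called in mock cells, 279 moved the same way in knockdown cells, and the gene far to the right, LOC395551, is at 8.57 and 4.44.

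Few genes were called at the early times. At 1 h, CCN2 and CYR61, which encode secreted proteins of the CCN family, rose in both genotypes. CCN2 went from 253 ± 27.8 to 583 ± 53.6 CPM in mock cells (1.20, SE 0.16, adjusted p = 0.000895) and from 268 ± 27.5 to 635 ± 12.3 CPM in knockdown cells (1.25, SE 0.16, adjusted p = 0.000496). CYR61 rose by 1.07 (SE 0.19, adjusted p = 0.0371) and 1.06 (SE 0.18, adjusted p = 0.0309). KLF6, a zinc finger transcription factor gene, rose in knockdown cells (0.60, SE 0.10, adjusted p = 0.0107) and was at 0.46 in mock cells (adjusted p = 0.232). These were the 2 genes called by edgeR in mock cells and the 3 called in knockdown cells, each with n = 3 per group. In mock cells the block within genotypes called 6, adding EGR1, KLF6 and PPP1R3C as higher and SOCS1 as lower (-0.80), chosen after their values were seen. Only CCN2 was called in mock cells without replicate 1 or 2 at 0 h or replicate 1 or 3 at 1 h, and in knockdown cells a single gene was called without any 1 of the replicates at 0 h or without replicate 2 or 3 at 1 h. CCN2 lies on chromosome 3 from 56836500 to 56839471 and CYR61 on chromosome 8 from 15923041 to 15925475 (GRCg7b).

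The immediate early list rose at 1 h in mock cells (2 of 47 called, 3 adjusted over the list alone, adjusted p = 2.16e-05) and knockdown cells (3 called, 3 adjusted over the list alone, adjusted p = 0.00104). Both calls were lost with an estimated correlation (adjusted p = 0.905 and 0.99). In mock cells the list's median turned to -0.04 without replicate 1 at 1 h and to -0.02 without replicate 2 at 0 h. In knockdown cells the call was also lost without replicate 1 (0.010) or replicate 2 (0.024) at 1 h. At 30 min edgeR called 0 genes in mock cells, with 646 at an unadjusted p under 0.05, and 0 in knockdown cells, with 228. DESeq2 and limma voom called 0 in both. The block within genotypes called 1 in mock cells, J6367_mgr01 (-0.56, adjusted p = 0.0102, chosen after its values were seen). The immediate early list in mock cells at 30 min had a median of 0.21 and an adjusted p of 0.000403 (0.847 with an estimated correlation). Its median was -0.02 without mock replicate 1 at 30 min, and the call was also lost without mock replicate 2 at 0 h (0.09) or mock replicate 3 at 30 min (0.23).

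Other lists also passed camera at the early times, with no member called in any of them. In mock cells at 1 h, ribosomal protein genes were at a median of 0.14 (adjusted p = 3.06e-19), kept in all 13 other settings with medians of 0.067 to 0.23, but not with an estimated correlation (adjusted p = 0.682). Nuclear genes of oxidative phosphorylation were at 0.076 (adjusted p = 2.16e-05, and 0.905 with an estimated correlation) and ranged from 0.030 without mock replicate 3 at 1 h (adjusted p = 0.413) to 0.16 without mock replicate 1 at 1 h. Mitochondrially encoded genes were at -0.20 (adjusted p = 9.45e-05, and 0.859 with an estimated correlation), at -0.12 without mock replicate 1 at 0 h (adjusted p = 0.129) at -0.081 without mock replicate 3 at 1 h (adjusted p = 0.0879) and at -0.31 without mock replicate 3 at 0 h. In knockdown cells at 1 h, ribosomal protein genes were at 0.070 (adjusted p = 3.21e-05, and 0.99 with an estimated correlation) and ranged from 0.046 without knockdown replicate 3 at 1 h (adjusted p = 0.154) to 0.12 without knockdown replicate 2 at 1 h. At 30 min in mock cells, ribosomal protein genes were at 0.079 (adjusted p = 0.000403), oxidative phosphorylation genes at 0.060 and histone genes at 0.25 (adjusted p = 0.0274 for both), each with an adjusted p of 0.847 with an estimated correlation, and these calls were lost in 2, 5 and 7 of 14 other settings, with medians from 0.041 to 0.13, 0.0017 to 0.12 and 0.10 to 0.36. At 30 min in knockdown cells, ribosomal protein genes were at -0.095 (adjusted p = 1.59e-09), oxidative phosphorylation genes at -0.090 (adjusted p = 1.34e-06) and mitochondrially encoded genes at -0.15 (adjusted p = 0.00193), each with an adjusted p of 0.83 with an estimated correlation. Without knockdown replicate 1 at 30 min the ribosomal protein list was at -0.024 and the oxidative phosphorylation list at -0.0038, with both calls lost, and without knockdown replicate 3 they were at -0.16 and -0.20. The mitochondrially encoded call was lost without knockdown replicate 2 at 0 h (-0.093) or knockdown replicate 2 (-0.13) or 3 (-0.058) at 30 min, and the list was at -0.28 without knockdown replicate 1 at 30 min.

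The last question was what IRF9 knockdown changed at each time apart from IRF9. Interferon-stimulated genes passed no test as a list, with medians of 0.00, -0.05, -0.01 and 0.07 at 0 h, 30 min, 1 h and 6 h and adjusted p-values of 0.689, 0.86, 0.642 and 0.316. The list as a whole did not rise in mock cells by 6 h either, so a loss of such a rise could not show here. IRF9 RNA also stayed at 46.2 to 66.1% of the mock level. These tests therefore do not say whether the list needs IRF9. STAT2, which encodes the partner of IRF9 in mammals, had a difference of -0.50 at 30 min (adjusted p = 0.285). At 6 h IFIT5 was 0.79 and TLR3 0.77 higher in knockdown cells, neither past the threshold (adjusted p = 0.777 for both). Apart from IRF9, edgeR called no gene at any time or on average. Without the low-count filter it called 26 on average, 2 higher and 24 lower. At 0 h, 1 h and 6 h it called 0, with 196, 302 and 799 genes at an unadjusted p under 0.05. DESeq2 and limma voom called 0 at 0 h and 1 h, and at 6 h limma voom called 0 and DESeq2 called 4 lower genes, HMBOX1, KIAA0753, LOC107053318 and PKD1, chosen after their values were seen.

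At 30 min, the comparison of knockdown with mock cells depended on single libraries. IRF9 was the 1 gene called by edgeR, with 1732 at an unadjusted p under 0.05. DESeq2 called 77, limma voom 0, and edgeR without the low-count filter 195. Without mock replicate 3 at 30 min, 741 genes were called, 618 of them lower, and without mock replicate 1 or knockdown replicate 1 or 2 at 30 min, 0 were called. Ribosomal protein genes were lower as a list at 30 min (median -0.16, adjusted p = 1.57e-09), as were nuclear genes of oxidative phosphorylation (-0.14, adjusted p = 4.93e-06) and histone genes (-0.38, adjusted p = 0.0303), all lost with an estimated correlation (adjusted p = 0.828). Without knockdown replicate 1 at 30 min the ribosomal protein list was at -0.097 (adjusted p = 0.000922) and the oxidative phosphorylation list at -0.040 (adjusted p = 0.0841). The oxidative phosphorylation list was at -0.23 without knockdown replicate 3 at 30 min (adjusted p = 3.01e-10). Without both replicate 1 libraries the ribosomal protein list was at -0.046 (adjusted p = 0.0112), and the histone list lost its call without mock replicate 1 (-0.14, adjusted p = 0.216), knockdown replicate 1 (-0.32, adjusted p = 0.0664) or knockdown replicate 2 at 30 min (-0.22, adjusted p = 0.0511). Adjusted over the list alone, 3 ribosomal protein genes, 1 gene of oxidative phosphorylation, 2 histone genes and 5 of 37 NF-kB genes were lower.

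Averaged over the 4 times, immediate early genes (median 0.10, adjusted p = 0.000375), heat shock genes (0.12, adjusted p = 0.00158) and sensing genes (0.08, adjusted p = 0.0462) were higher and extracellular matrix genes lower (-0.15, adjusted p = 8.34e-06) in knockdown cells as lists. Each call was lost with an estimated correlation (adjusted p = 0.797). The heat shock list lay at a median of -0.24 to -0.35 (log2) in the 4 libraries of mock replicate 2 relative to the other mock libraries of the same time. Without these 4 libraries the averaged medians were -0.03 for immediate early genes, -0.01 for extracellular matrix genes, 0.0092 for heat shock genes (adjusted p = 0.588) and 0.019 for sensing genes (adjusted p = 0.43). The call of sensing genes was lost in 12 of 30 other settings. Without mock replicate 2 at 30 min alone, the medians were 0.055 for immediate early genes (adjusted p = 0.0186) and 0.077 for heat shock genes (adjusted p = 0.00662). At 0 h the immediate early (0.18), heat shock (0.12), cell cycle (-0.06) and extracellular matrix (-0.14) lists passed camera, and none did with an estimated correlation (adjusted p = 0.77). All 4 calls were lost without mock replicate 2 at 0 h, with medians of 0.050, 0.036, -0.0057 and -0.019. The heat shock call also ended without knockdown replicate 2 at 0 h and the cell cycle call without knockdown replicate 1 at 0 h, with medians of 0.11 (adjusted p = 0.0525) and -0.050 (adjusted p = 0.172) that moved little. Without mock replicate 1 at 0 h the immediate early list was at 0.27 and the cell cycle list at -0.11, and without knockdown replicate 3 at 0 h the heat shock list was at 0.076 (adjusted p = 0.0434). Nor did those of 1 h, immediate early (0.14) and ribosomal protein genes (-0.06), with an adjusted p of 0.775 with an estimated correlation. At 1 h the immediate early call also ended without mock replicate 2 (0.041, adjusted p = 0.723), knockdown replicate 1 (0.12, adjusted p = 0.125) or knockdown replicate 2 (0.11, adjusted p = 0.419). That of ribosomal protein genes ended without mock replicate 2 (-0.044), mock replicate 3 (0.027) or knockdown replicate 2 (-0.0055). Without mock replicate 1 at 1 h the immediate early list was at 0.27 and the ribosomal protein list at -0.14.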

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

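The test of IRF9 levels in the 4 libraries of mock replicate 2 was chosen only after the result was seen.

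In 6 cases a gene list passed camera's test of the interaction, a difference between knockdown and mock cells in the change from 0 h, although no single gene did. None of the 6 passed with an estimated correlation. At 30 min the median interaction was -0.31 for immediate early genes (adjusted p = 0.000636), -0.17 for ribosomal protein genes (1.76e-09) and -0.20 for nuclear genes of oxidative phosphorylation (8.84e-06), with an adjusted p of 0.899 for each with an estimated correlation. At 1 h it was -0.070 for ribosomal protein genes (adjusted p = 9e-04, and 0.922 with an estimated correlation). At 6 h it was 0.15 for ribosomal protein genes (6.36e-13) and 0.16 for oxidative phosphorylation (3.39e-06), with an adjusted p of 0.951 for both with an estimated correlation. The calls at 6 h stayed in all 19 other settings, fry and the estimated correlation not counted. That of ribosomal protein genes at 30 min stayed past the threshold in all 20, but the median shrank to -0.10 without knockdown replicate 1 at 30 min and to -0.057 without both replicate 1 libraries at 30 min. The immediate early call at 30 min ended without mock replicate 1 at 30 min (-0.076, adjusted p = 0.174), mock replicate 2 at 0 h (-0.16, 0.19) or mock replicate 3 at 30 min (-0.24, 0.0568), and was at -0.054 without both replicate 1 libraries at 30 min (0.479) and -0.47 without mock replicate 2 at 30 min. Leaving out both was chosen after seeing the data. The oxidative phosphorylation call at 30 min ended without knockdown replicate 1 at 30 min (-0.061, 0.0792) and without both replicate 1 libraries (-0.056, 0.0966). It stayed, with a smaller median, without mock replicate 3 at 30 min (-0.11, 0.0123) and without knockdown replicate 3 at 0 h (-0.13, 0.000806). The ribosomal protein call at 1 h ended in 6 of 19 settings, with medians over all 19 from -0.16 to -0.0010, the last without mock replicate 3 at 1 h (adjusted p = 0.946).

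The 4 libraries of mock replicate 2 stood apart from the other 20 on the first principal component, and the heat shock list and HSPA2 were lower in them. The tables argue against a wrong genotype label, since the lowest IRF9 level among the 4 was 27.2 CPM and the highest of the 12 knockdown libraries was 23.2 CPM. They also argue against depth, since the gap to the nearest other library was 21.8 after thinning every library to 12174030 counts and 20.9 before, against an SD of 7.11 among the others. Leaving out the 100 most abundant genes and the heat shock list left a gap of 20.7 (SD 7.30), so those genes were not the whole cause. An unlabelled batch or culture may underlie the gap of 20.9, and no biological explanation was tested.

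Other splits of the libraries were fitted for each count. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real split of 6 h against 0 h called 282 genes in mock cells and the highest other split 1, and in knockdown cells 224 and 0, so that 1 of 10 splits reached the real count in each. At 1 h the real counts were 2 in mock and 3 in knockdown cells and the highest other 0, again 1 of 10 splits. For knockdown against mock at 30 min, 2 of 10 splits gave at least 1 gene, the real count, and the highest other split gave 1. Where the real count was 0, which held for knockdown against mock at 0 h, 1 h and 6 h and for 30 min against 0 h in both genotypes, all 10 splits were as large by construction, with a highest other count of 1 for knockdown against mock at 6 h and 0 elsewhere.

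For knockdown against mock averaged over the 4 times, 2 of 100 splits gave at least the real count of 1 gene. The highest other split called 9 genes, several times the real count, and the rest called 0. A structure of the samples may lie behind that 1 split, but what it shared was not tested. These splits moved libraries singly, although mock libraries of the same number deviated together across the times, so they do not exclude chance for that count. For the interactions the real count was 0 at each time, 100 of 100 splits were as large by construction, and the highest other counts were 1 at 30 min, 0 at 1 h and 0 at 6 h, so these splits say nothing about chance.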

How the results depend on the processing

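The block within genotypes and the settings that leave out mock replicate 2 or both replicate 1 libraries at 30 min were chosen after seeing the data. The 6 h responses kept their direction throughout. The cytokine, NF-kB and sterol lists stayed past the threshold of camera in both genotypes in all 13 settings, which leave out fry. All 282 and 224 called genes were shared by DESeq2 and the replicate block. Of 96 calls of named genes, none reversed; 1 was lost with RLE scaling, 5 without the filter, 0 with DESeq2 or either block, 4 with limma voom, 10 with only the groups compared and 8 without mock replicate 2, and 121 calls were lost over all fits without 1 library. The interaction counts stayed at 0 in every setting. The slope of the 6 h responses ran from 0.50 to 0.74 without 1 library. Its jackknife error is computed from those same slopes, so it is no test of them. Genes near the floor of 3 counts, and folds under 1.5, are at the limit of this depth and number of libraries.

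For knockdown against mock at 30 min, where 1 gene was called, the count was 195 without the filter, 77 with DESeq2, 0 with limma voom, 0 with only the groups compared, 6 without mock replicate 2 and 0 without both replicate 1 libraries. It ran from 0 to 741 without 1 library, being highest without mock replicate 3. IRF9 at 30 min was -1.06 with limma voom (adjusted p = 0.0502), -1.10 with only the groups compared (0.621) and -0.73 without both replicate 1 libraries (0.993), and ran from -1.24 to -0.87 without 1 library. At 6 h DESeq2 called 4 genes, and leaving out 1 library gave 0 to 2, with 2 without mock replicate 3 at 6 h. Averaged over times, 26 genes were called without the filter.

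In mock cells at 30 min, 3 genes were called without the filter and 1 with the block within genotypes. At 1 h the count in mock cells was 4 without the filter, 5 with DESeq2, 6 with the block within genotypes and 1 without mock replicate 2, and 1 to 2 without 1 library. In knockdown cells at 1 h it was 5 with DESeq2, 7 with only the groups compared, 7 with the block within genotypes and 5 without mock replicate 2, and 1 to 2 without 1 library. At 6 h it was 155 with only the groups compared and 699 with the block within genotypes in mock cells. In knockdown cells, where the numbers were not taken to pair the samples, it was 354 with the replicate block and 656 with the block within genotypes. It was 843 with only the groups compared, 378 without mock replicate 2, and 120 to 150 without 1 library. In mock cells at 6 h the replicate block called 388, with all 282 genes of the main fit among them. It left the counts of the other comparisons unchanged.

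Some list medians turned, with the call lost. Ribosomal protein genes, knockdown against mock at 1 h, reached 0.027 without mock replicate 3 (range -0.14 to 0.027 without 1 library). Without mock replicate 2, the averaged difference was -0.032 for immediate early genes and -0.014 for extracellular matrix genes, the latter with the direction of its test turned. Immediate early genes in mock cells at 30 min were at -0.021 without both replicate 1 libraries and from -0.021 to 0.38 without 1 library, and at 1 h from -0.038 to 0.30. Fits with fewer libraries or only 2 groups estimate the spread from fewer samples. They also leave out the spread of the other groups, which was unequal. Pairs of knockdown libraries differed by a chi-square per degree of freedom of 3.11 to 23.4, and pairs of mock libraries by 9.88 to 56.9. Knockdown cells at 6 h gained calls with only the groups compared (843 against 224 in the main fit). Apart from that, the cause was not tested.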

Other observations

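The tests of sterol and interferon-stimulated genes in this part were chosen only after the results were seen.

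ANGPTL4 and ADM rose at 6 h in both genotypes. ANGPTL4, which encodes an inhibitor of lipoprotein lipase, went from 135 ± 41.2 to 430 ± 111 CPM in mock cells (1.67, SE 0.24, adjusted p = 7.64e-05, edgeR, n = 3) and rose by 1.72 in knockdown cells. ADM, the gene for the vessel-widening peptide adrenomedullin, rose by 1.07 and 1.12. VEGFA rose in knockdown cells (0.73, adjusted p = 0.022) and was at 0.62 in mock cells (adjusted p = 0.056). They were the only genes called among 35 for glycolysis and hypoxia, 2 in mock and 3 in knockdown cells (4 and 3 adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.755 and 0.358). CD3E, which encodes a chain of the T cell receptor complex, rose from 10.7 ± 1.22 to 23.7 ± 2.78 CPM in mock cells (1.16, SE 0.17, adjusted p = 0.000105, edgeR, n = 3) and by 1.00 in knockdown cells (adjusted p = 0.000661). It was the 1 called gene among 8 tested leukocyte markers (1 adjusted over the list alone). PTPRC, the pan-leukocyte gene, reached at most 2.45 CPM as a group mean, CD3D 0.967 CPM, CSF1R 1.35 CPM, CD14 1.62 CPM and CTSS 0.680 CPM, while LAPTM5 reached 7.84 CPM and CD74 9.53 CPM. Of 6 endothelial markers, 2 were higher adjusted over the list alone in each genotype, and the list passed camera (adjusted p = 0.0165 in mock and 0.0101 in knockdown cells) but not with an estimated correlation (adjusted p = 0.0583 and 0.0508). In mock cells it also failed camera without the low-count filter (adjusted p = 0.271), with only the groups compared (0.0518), without mock replicate 1 at 0 h (0.0666) or without mock replicate 2 at 6 h (0.128). FLT1, the most changed of them among well-expressed genes, was at 0.51 in both (adjusted p = 0.0503 and 0.0686).

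Genes of protein synthesis and respiration moved by small amounts as lists. At 6 h the 65 ribosomal protein genes had a median of 0.24 in knockdown cells (1 called, RPL19, and 28 higher adjusted over the list alone; adjusted p = 6.18e-24, and 0.211 with an estimated correlation) and 0.08 in mock cells (0 called, 0 adjusted over the list alone; 0.00111, and 0.787). The call in mock cells was also lost without mock replicate 3 at 6 h (0.055, adjusted p = 0.1). The 13 mitochondrially encoded genes were at -0.33 in knockdown cells (adjusted p = 1.1e-05, and 0.325 with an estimated correlation), and at -0.17 without knockdown replicate 3 at 6 h (adjusted p = 0.015). In knockdown against mock cells at 6 h, ribosomal protein genes were at 0.17, oxidative phosphorylation genes at 0.16, immediate early genes at 0.18, heat shock genes at 0.11, extracellular matrix genes at -0.21 and mitochondrially encoded genes at -0.19, and no call held with an estimated correlation (adjusted p = 0.758). Without mock replicate 2 at 6 h the immediate early (0.044), heat shock (0.042), extracellular matrix (-0.052) and mitochondrially encoded (-0.15) lists no longer passed camera either. The mitochondrially encoded list was at -0.077 without knockdown replicate 3 at 6 h (adjusted p = 0.427) and -0.31 without knockdown replicate 2 at 6 h. Without mock replicate 1 at 6 h the immediate early list was at 0.29, and without mock replicate 3 at 6 h the heat shock list at 0.17.

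Sterol synthesis genes rose at 6 h in both genotypes. An error of scaling is argued against, since even the lower quartile of the list lay 0.48 (log2) above the median of all genes in mock cells. Time in culture or handling without poly(I:C) cannot be told apart from an effect of poly(I:C): the list's median was 1.04 in knockdown and 0.88 in mock cells, and no unstimulated 6 h samples were analysed here. A response of sterol synthesis to poly(I:C) is a hypothesis that this design leaves open.

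Few interferon-stimulated genes rose at 6 h. In mock cells HELZ2, CASP8, NLRC5 and IFI6 were called higher among 48 tested. That is a larger share than the 252 higher among all 13000 genes, so only a rise of most members was lacking. Low counts are argued against for the 34 members with at least 5 CPM, which had an upper quartile of 0.047 (log2) in mock cells, with a median SE of 0.16; members under that level stay open. A candidate explanation is that the cells held next to no interferon transcripts by 6 h. The highest level of 5 interferon genes in any 6 h library was 0.0708 CPM, under the floor of 3 counts, and IFNA3, IFNG, IFNKL1 and IFNL3A had 0 counts in all 24 libraries (chosen after their values were seen). This cannot be told apart from a loss of reads shared by near-identical interferon genes, or from interferon made at times that were not sampled.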
